A study of Mus musculus with 6 samples.

How the data were processed

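Total RNA of mouse embryonic fibroblasts was sequenced as paired reads, with 1 library for each of 6 groups (floxed or deleted Claspin, each growing, starved or released). Groups were taken from the sample titles. Per the labels' protocols, the medium held 15% fetal bovine serum, starvation lasted 24 h in serum-free medium, and released cells were harvested 14 h after serum was added. Floxed and deleted cells differ in exposure to Ad-Cre as well as in Claspin, and no Ad-Cre-treated cells with intact Claspin are among the 6 libraries.

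The deposited files are mapping reports, not tables of genes. Per the file headers, each report counts the reads of a trimmed paired library that mapped in pairs, mapped in broken pairs or did not map. It also counts fragments by class (exon, exon-exon, intron), reads by their number of match positions, and fragments by the distance spanned by the pair. Per the file headers, an intact pair was counted as 1 fragment and broken pairs were ignored. The longest read was 150 bp. The reference had 22 sequences of 2725537669 bp in all, with 53379 genes and 111395 transcripts, and 19539 of the genes had 0 transcripts. The mapping program and its settings are not given in the sources used here. The reports do not define the fragment classes beyond their names, and the exon class is called within-exon here. Fragments outside genes have no class of their own in the reports. The submitters' processing notes name the builds GRCm38, mm10 and GRCm39 without saying which was used for what. The deposited values are whole-number counts that were not normalized, beside percentages made by the authors' software, which served only as a check. Percentages recomputed from the counts differed from the printed ones by at most 0.0049 points.

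The report deposited for the deleted released sample covers all 6 libraries pooled. Its input list names them, and its total of 349152522 reads equals the sum of the reads of the 6 libraries. The values of the deleted released library were therefore computed by subtracting the reports of the other 5 libraries from the pooled report. This was checked on fragments spanning more than the upper distance limit of that library, 373 bp, of which it should have none. In the 9 distance bins past this limit the remainder was at most 139 fragments in any bin, and -374 fragments in sum, or -0.0150% of the 2486729 pooled fragments there. No other class had a negative remainder. A further 5 reports deposited with the released floxed sample were identical to reports deposited for other samples and were not used.

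Exon-exon, within-exon and intron shares are relative to counted fragments, and shares by number of match positions are relative to reads mapped in pairs. Shares of mapped, broken-pair and unmapped reads are relative to all reads after trimming. Each share has a 95% Wilson binomial interval and each difference of shares Newcombe's interval, for counting error only. The mean paired distance was computed from bins of 5 bp, each placed at its middle base, up to the upper limit that each report gives. Deleted and floxed cells were compared within each condition, and conditions within each genotype, as differences in percentage points. An exact two-sided permutation test swapped the genotypes within conditions (8 arrangements), and its p-values were adjusted over 13 measures by the Benjamini-Hochberg method. Some of the 13 repeat another or are its complement, such as mapped and unmapped reads, so fewer than 13 are distinct. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

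The comparisons, the tests and the first set of alternatives were fixed before the data were examined. These alternatives were other denominators, uniquely mapped fragments only, pairs only, log2 odds ratios, and leaving out each culture condition. The pooled report taken as it stands, exonic fragments as denominator and a common upper distance limit of 364 bp were added after the data had been seen. Classes with at least 1% of reads or fragments in any library were to be named. Planned comparisons of single genes and of gene lists for replication, serum response, quiescence, the p53 response and PI3K-PDK1-mTOR signalling, the pathway in the study's title, were not run, because the values used are not per gene.

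For 2 checks in the closing section, the GENCODE M21 annotation of GRCm38 was used, which has 55450 genes and 141767 transcripts and so is not the annotation of the reports. Merged exons of its 21951 protein-coding genes cover 97366161 bp and the remainder of those genes 976821330 bp, a ratio of 0.0997. Windows of 150 bases from the transcripts of 13 mitochondrial protein-coding genes (9466 windows) and of 1318 nuclear protein-coding genes whose transcripts all have 1 exon (389158 windows, 1 every 5 bases) were searched for exact copies in all annotated transcripts, on both strands.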

Results

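RNA was sequenced from mouse embryonic fibroblasts carrying a floxed and a null allele of Claspin, the gene for an adaptor protein of DNA replication forks through which the kinase ATR activates the checkpoint kinase Chk1. Cells that kept the floxed allele are called floxed here. Cells of the Claspin-null genotype, obtained by treatment with Ad-Cre, an adenovirus that delivers Cre recombinase, are called deleted. Both genotypes were sampled in 3 culture conditions: growing in medium with 15% fetal bovine serum, after 24 h without serum (starved), and 14 h after serum was added back to starved cells (released). The 6 groups held 1 library each. There is therefore no spread between replicates, no difference below has a replicate check, and each comparison of a pair of libraries compares those libraries rather than the conditions. The measurements are numbers of reads and fragments in each mapping class of the authors' mapping reports. Values of single genes were not analysed here, so the level of Clspn, the mouse Claspin gene, was not checked in any library.

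The libraries held between 45000008 reads (deleted released) and 61863532 reads (floxed starved) after trimming. Read pairs mapped as intact pairs were counted as fragments, which gave 21459390 counted fragments in the deleted released library and between 28329463 and 29269142 in the other 5. At this depth the 95% Wilson interval of any share extended at most 0.021 percentage points to either side, and Newcombe's interval of any difference at most 0.028 points. These intervals cover counting error only, since reads amplified by PCR are not independent molecules and cultures were not repeated. Shares of reads count both mates of a pair as separate reads, so their intervals are too narrow. The values of the deleted released library were obtained by subtraction from a report of all 6 libraries pooled.

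The first question was how the withdrawal and return of serum changed the composition of the RNA in each genotype. Starved cells had a smaller share of exon-exon fragments, which join exons of a spliced transcript, than growing cells of the same genotype. In floxed cells these fragments made up 50.7% of counted fragments during growth, 39.8% after starvation and 51.5% after release. In deleted cells the shares were 51.1%, 35.1% and 49.2%, in the same order. Starved minus growing, the difference was -10.9 points in floxed cells and -16.0 points in deleted cells. Released minus starved, it was 11.7 points in floxed cells and 14.1 points in deleted cells, equal in size to 107% and 88.2% of the preceding difference.

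**Figure D1:**
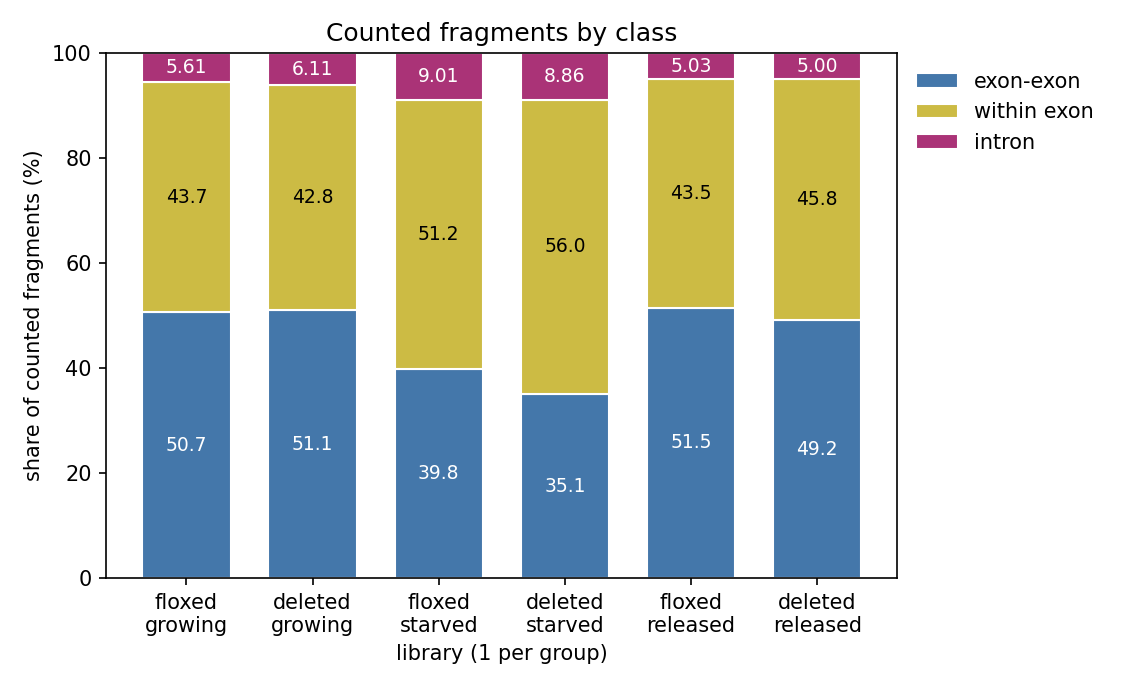
Stacked bars give the share of counted fragments (%, vertical axis) in the exon-exon, within-exon and intron classes for each library (horizontal axis, 1 library per group, no error bars). Both starved libraries have the smallest exon-exon shares, 39.8% and 35.1%, against 49.2% to 51.5% in the other libraries.

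Fragments lying within a single exon took up most of the difference. Their share was 43.7% in growing, 51.2% in starved and 43.5% in released floxed cells, and 42.8%, 56.0% and 45.8% in deleted cells. Intron fragments, which derive from unspliced or partly spliced RNA, from other transcripts inside introns or from genomic DNA, also had a larger share in starved cells. The intron share of floxed cells was 5.61% during growth, 9.01% after starvation and 5.03% after release. That of deleted cells was 6.11%, 8.86% and 5.00%. The starved share was 1.60 times the growing share in floxed cells and 1.45 times in deleted cells.

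Reads with exactly 2 match positions in the reference, which arise from sequence present in a pair of copies, were also more frequent in starved cells. They made up 8.75% of reads mapped in pairs in growing, 12.3% in starved and 8.58% in released floxed cells. The corresponding shares in deleted cells were 8.99%, 14.8% and 9.36%. Reads with 3 to 10 match positions differed far less, at 2.46%, 2.57% and 2.44% in floxed cells and 2.49%, 2.42% and 2.18% in deleted cells. Reads with exactly 3 positions made up between 1.41% and 1.55% of reads mapped in pairs in each library. Reads with a single position accounted for 85.2% and 82.8% of those mapped in pairs in floxed and deleted starved cells, and for 88.5% to 89.0% in the other 4 libraries. Non-specific fragments, those with more than 1 match position, made up 11.2%, 14.8% and 11.0% of counted fragments in growing, starved and released floxed cells. In deleted cells they made up 11.5%, 17.2% and 11.5%.

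**Figure D2:**
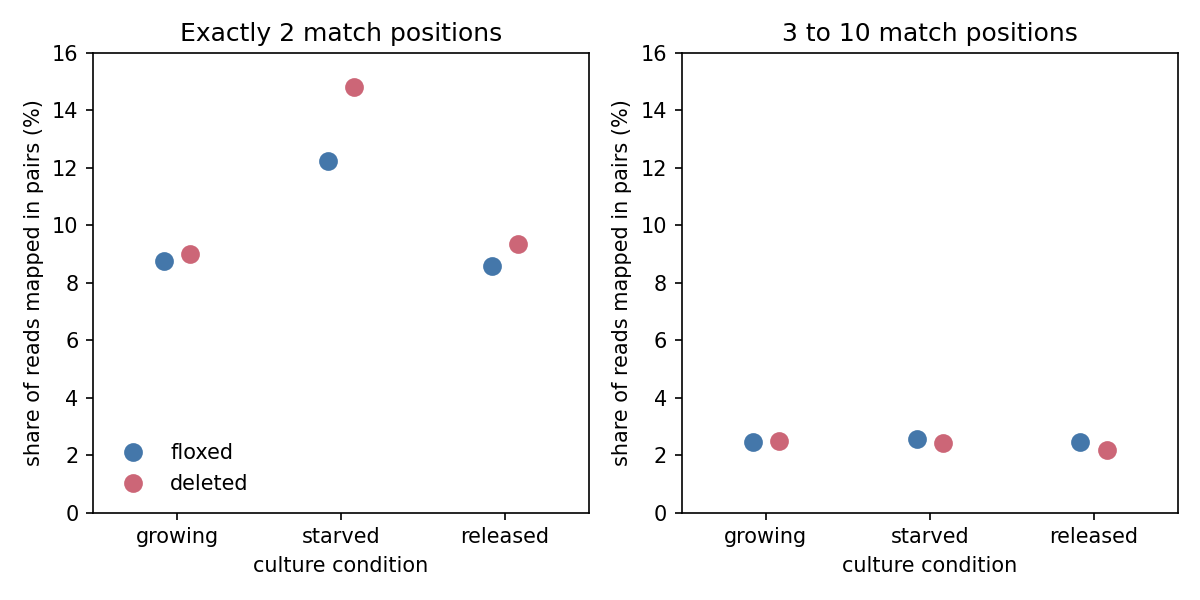
Points give the share of reads mapped in pairs (%, vertical axis) with exactly 2 (left) and with 3 to 10 (right) match positions in growing, starved and released cells (horizontal axis), 1 library per point, blue for floxed and red for deleted cells. With exactly 2 positions the starved libraries lie highest, at 12.3% and 14.8%, while with 3 to 10 positions all libraries lie between 2.18% and 2.57%.

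Unmapped reads were also most frequent in starved cells. They made up 1.60% of reads in growing, 2.39% in starved and 1.69% in released floxed cells, and 1.65%, 2.39% and 1.75% in deleted cells. Fragments were shorter in starved and released than in growing cells. The mean distance spanned by a read pair was 238 bp in growing, 224 bp in starved and 225 bp in released floxed cells. In deleted cells it was 247 bp, 228 bp and 224 bp. Each library had its own upper limit on this distance, between 368 and 416 bp, which affects its mean. Released minus starved, the mean differed by 1.11 bp in floxed and -3.86 bp in deleted cells. Over distances up to 364 bp, which every library covers, these differences were 2.41 and -1.24 bp. Starved minus growing, they were then -10.4 and -14.3 bp.

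**Figure D3:**
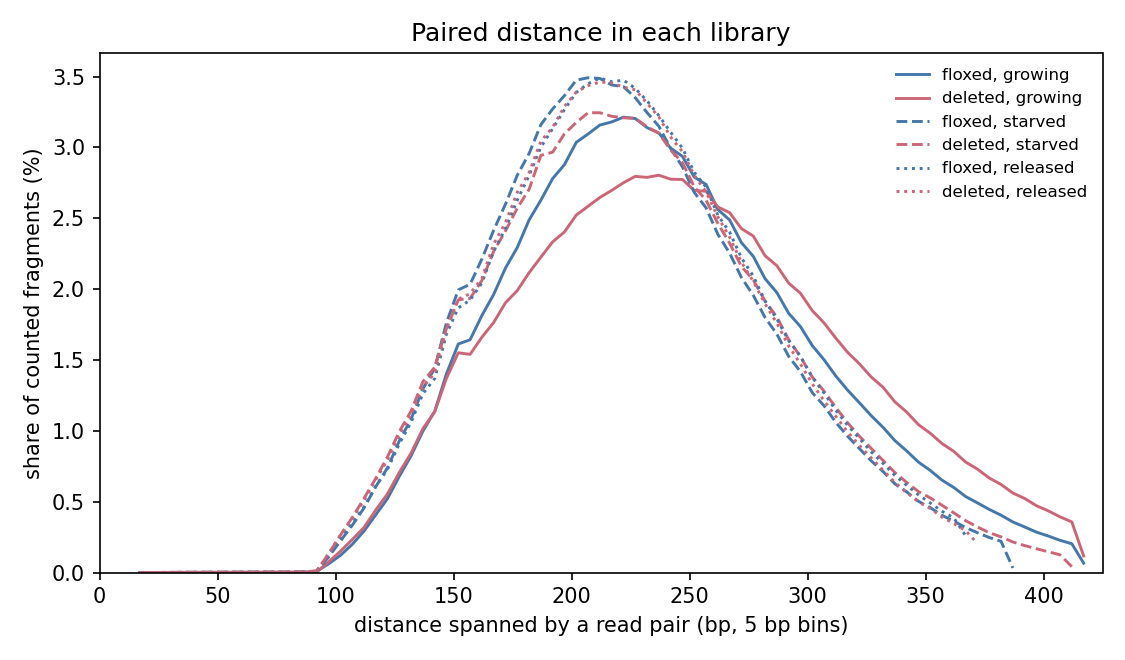
Lines give the share of counted fragments (%, vertical axis) at each distance spanned by a read pair (bp, horizontal axis, 5 bp bins), 1 line per library, with colour for genotype and line style for culture condition. The growing libraries have longer mean distances, 238 bp and 247 bp, than the starved and released libraries, whose means lie between 224 bp and 228 bp. Each line ends at the upper limit of its own library, between 368 and 416 bp.

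The next question was how deletion of Claspin changed these shares under each condition. The exon-exon share of deleted and floxed cells was close during growth and lower in deleted cells after starvation and after release. Deleted minus floxed, the difference was 0.353 points in growing, -4.71 points in starved and -2.33 points in released cells. The within-exon share differed by -0.851, 4.86 and 2.36 points. The exon-exon direction in growing cells was not stable, since with all fragments in the denominator, uncounted ones included, the difference there was -0.460 points. As a share of exonic fragments, the exon-exon difference in growing cells was 0.661 points. Taking the pooled report itself for the deleted released sample gave an exon-exon difference of -5.39 points for that condition. That report mixes all 6 libraries, the starved ones included, so this value does not estimate the deleted released cells alone. With all fragments in the denominator, the within-exon difference in growing cells was -1.48 points.

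Across the 3 conditions the mean exon-exon difference was -2.23 points, with deleted cells lower in 2 of 3 conditions. An exact two-sided permutation test that swapped genotypes within conditions gave p = 0.5 (adjusted p = 0.722 by the Benjamini-Hochberg method over 13 measures). With 8 arrangements the smallest p this test allows is 0.25, so it cannot pass 0.05 for any measure. The mean was -0.987 points without the starved pair and -3.52 points without the growing pair.

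Reads with exactly 2 match positions were more frequent in deleted than floxed cells in 3 of 3 conditions. The difference was 0.240 points in growing, 2.55 points in starved and 0.778 points in released cells, with a mean of 1.19 points. The same exact permutation test gave p = 0.25, the smallest it allows (adjusted p = 0.722). As a share of all reads the growing difference was 0.0894 points, and the mean without the starved pair was 0.509 points. Taking the pooled report itself, which mixes all 6 libraries, for the deleted released sample gave 1.91 points for that condition. Non-specific fragments, which comprise this class and that with 3 to 10 positions and so are no separate result, differed by 0.270, 2.39 and 0.516 points. With all fragments in the denominator their difference in growing cells was 0.0787 points.

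In points the intron share differed little between genotypes, though in growing cells the deleted share was 1.09 times the floxed share. Deleted minus floxed, it was 0.498 points in growing, -0.149 points in starved and -0.0292 points in released cells, with a mean of 0.107 points (exact permutation p = 1, adjusted p = 1). The mean was -0.0893 points without the growing pair, 0.235 points without the starved pair and 0.174 points without the released pair. Among uniquely mapped fragments the last 2 differences were 0.127 and 0.210 points, so the intron share of deleted cells was then higher in every condition. After release the difference was 0.00676 points with all fragments in the denominator and 1.64 points with the pooled report, which mixes all 6 libraries. Unmapped reads differed by at most 0.0600 points in any condition.

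Reads in broken pairs, in which the mates were not placed as a pair, were most frequent in growing deleted cells, at 4.25%. Growing floxed cells had 2.74%. The starved libraries had 3.13% (floxed) and 2.71% (deleted), and the released libraries 3.62% and 2.87%. Reads mapped in pairs made up 95.7% of reads in growing floxed and 94.1% in growing deleted cells, 94.5% and 94.9% in starved cells, and 94.7% and 95.4% in released cells. Deleted minus floxed, the mean paired distance was 8.87 bp in growing, 3.83 bp in starved and -1.15 bp in released cells (exact permutation p = 0.5, adjusted p = 0.722). Over distances up to 364 bp, the differences were 6.01, 2.14 and -1.51 bp.

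The last question was whether the response to starvation and to release differed with the genotype. The deleted minus floxed difference in the exon-exon share was lower in starved than in growing cells, with a difference of differences of -5.06 points. For released against growing cells it was -2.68 points, and -1.41 points with all fragments in the denominator. For reads with exactly 2 match positions the corresponding values were 2.31 and 0.538 points. For the intron share they were -0.648 and -0.528 points, the latter -0.351 points among uniquely mapped fragments. With the pooled report, the values for released against growing cells were -5.74 points (exon-exon), 1.67 points (2 positions) and 1.15 points (intron). That report mixes all 6 libraries, so these values are not of the deleted released library alone. Without replicates these are values only and were not tested.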

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

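The tests of explanations in this part were chosen after the results were seen. The differences of differences had been planned.

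For 7 of the 9 classes of reads or fragments compared, the deleted minus floxed difference changed sign. Its signs in growing cells and in starved or released cells were opposite, each beyond its counting interval. With 1 library per group these contrasts were not tested. They are not separate results, since exon-exon, within-exon and intron fragments add up to all counted fragments. Likewise reads mapped in pairs, in broken pairs and unmapped add up to all reads. Starved less growing, the difference of differences was -5.06 points for exon-exon fragments, 5.71 points for within-exon fragments, -0.648 points for intron fragments and -0.186 points for reads with 3 to 10 match positions. Released less growing, the values were -2.68, 3.21, -0.528 and -0.291 points for the same classes. Reads mapped in pairs gave 1.98 points for starved less growing and 2.25 points for released less growing. Reads in broken pairs gave -1.92 and -2.26 points. Unmapped reads gave -0.0573 points for starved less growing and 0.0664 points for released less starved. Their deleted minus floxed difference in starved cells was only -0.0064 points, with an interval of -0.0118 to -0.000965. That interval counts both mates of a pair and an interval over pairs was not computed, so this sign is uncertain. The opposite signs of 3 classes depended on the setting. Those of the intron share were absent among uniquely mapped fragments, where deleted cells were higher by 0.561, 0.127 and 0.210 points in growing, starved and released cells. With all fragments as denominator, the intron difference after release was 0.00676 points and had the sign of that in growing cells. It had that sign with the pooled report too, at 1.64 points, but that report mixes all 6 libraries. Those of the exon-exon share were absent with all fragments as denominator, where deleted cells differed by -0.460, -4.30 and -1.87 points. Those of reads with 3 to 10 match positions were absent with all reads as denominator, at -0.0107, -0.138 and -0.233 points.

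The first pattern is the lower exon-exon share of starved cells in both genotypes. Shorter fragments, which span fewer junctions, are argued against as its cause, because released cells had an exon-exon share higher than starved cells by 11.7 points (floxed) and 14.1 points (deleted), while their mean paired distance up to a common limit differed by 2.41 and -1.24 bp. Unspliced RNA or genomic DNA of genes with introns, as the source of the added within-exon fragments, is argued against too. Among uniquely mapped fragments, each class taken per exon-exon fragment, the within-exon gain was 3.44 (floxed) and 5.17 (deleted) times the intron gain. Exons cover 0.0997 times the length of introns, a ratio from another annotation and not weighted by expression. Sequence without introns adds no intron fragments, so this comparison does not cover it. Fragments with several match positions alone are not enough, as the starved minus growing difference among uniquely mapped fragments was -10.7 and -15.2 points. A shift towards transcripts with few or long exons during starvation may account for the within-exon part, as a hypothesis that counts per gene would test, and the origin of the added intron fragments stays open.

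The second pattern is the lower exon-exon share of deleted than floxed cells after starvation, by -4.71 points. Shorter fragments in deleted cells are argued against, since their mean paired distance was longer by 3.83 bp, and by 2.14 bp up to a common limit. Exposure to Ad-Cre cannot be told apart from the loss of Claspin, since 0 floxed libraries carry that treatment in their labels. Variation between single cultures cannot be told apart either, because no group has a second library; growing and released cells of a genotype differed by up to 1.89 points. A stronger response of deleted cells to starvation is thus an untested hypothesis among these.

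The third pattern is the share of reads in broken pairs, highest in growing deleted cells. If an upper limit on the distance between mates broke pairs, libraries with more fragments next to that limit would have more broken pairs. Over the 6 libraries, the share of fragments in the last full distance bin and the share of broken pairs gave Pearson's r = 0.789 (exact permutation p = 0.0611) and Spearman's rho = 0.886 (exact permutation p = 0.0333). This was the only relation computed in its family, so the adjusted p of Pearson's r equals the raw one. The p of Spearman's rho was not adjusted for the use of a second coefficient. Without the 2 libraries whose last-bin share lay farthest from its median, starved deleted and released floxed, r was 0.803 (exact permutation p = 0.125 over 4 libraries). Growing deleted cells, which had the highest share of broken pairs, were kept in that value. The limit is therefore a possible explanation that these few libraries cannot settle, and genotype and condition stay open beside it.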

How the results depend on the processing

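The pooled report taken as it stands, exonic fragments as denominator and a common distance limit were chosen after the data were seen; the other alternatives were planned. Of 142 alternative values, with log2 odds ratios of single differences left out, 131 kept their direction and 11 reversed. This count overstates stability. It includes leave-one-out means of the 2-position and non-specific shares, which could not reverse because their differences were positive in 3 of 3 conditions. It also includes values from the pooled report, which holds the compared libraries themselves. A further 49 values, the log2 odds ratios of single differences, have the sign of the difference by construction and say nothing about stability. Every starved minus growing and released minus starved difference in the exon-exon, intron and 2-position shares kept its direction. At this depth each main difference exceeded its counting interval. The intron difference after release with all fragments as denominator, 0.00676, is given without an interval, so its sign is uncertain. The main intron difference there was -0.0292, and its interval of -0.0414 to -0.0170 extends further than 0.00676 to either side of it. Intervals of shares of reads count both mates of a pair and are too narrow. The difference in unmapped reads of starved cells exceeded its own interval only narrowly. The lack of replicates limits all values. Replicate numbers pair no libraries, since each group held 1, and the permutation test paired genotypes by culture condition. Other pseudocounts, filters and normalizations for single genes were not run, since the values used are not per gene. As log2 odds ratios, 6 of 6 differences of differences kept their direction. Differences below are in points, in the order growing, starved and released for deleted minus floxed.

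With all fragments as denominator, exon-exon gave -0.460 (reversed), -4.30 and -1.87, and intron 0.381, -0.104 and 0.00676 (reversed). Starved less growing and released less growing, these gave -3.84 and -1.41 for exon-exon and -0.485 and -0.374 for intron. For released minus starved, exon-exon gave 11.2 (floxed) and 13.6 (deleted) and intron -3.75 and -3.64. For starved minus growing, exon-exon gave -14.7 in deleted cells, and intron 3.14 (floxed) and 2.66 (deleted). With all reads as denominator, the 2-position share gave 0.0894, 2.47 and 0.801. The differences of differences were 2.38 and 0.712. Starved minus growing was 3.21 (floxed) and 5.59 (deleted), and released minus starved -3.45 and -5.12. The difference in reads with 3 to 10 positions reversed in growing cells, to -0.0107.

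Among uniquely mapped fragments, exon-exon gave 0.437, -4.09 and -1.88, and intron 0.561, 0.127 (reversed) and 0.210 (reversed), with differences of differences of -4.53 and -2.31 for exon-exon and -0.434 and -0.351 for intron. Starved minus growing was -10.7 (floxed) and -15.2 (deleted) for exon-exon and 3.68 and 3.25 for intron. Released minus starved was 11.6 and 13.8 for exon-exon and -4.09 and -4.01 for intron. With exonic fragments as denominator, exon-exon gave 0.661, -5.24 and -2.47, and -5.90 and -3.13 as differences of differences. Starved minus growing was -9.98 and -15.9, and released minus starved 10.5 and 13.3.

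With the pooled report in place of the deleted released library, deleted minus floxed after release was -5.39 for exon-exon, 1.64 (reversed) for intron and 1.91 for the 2-position share. Less growing, these were -5.74, 1.15 (reversed) and 1.67. Released minus starved was 11.0, -2.19 and -4.31, and 0.0224 (reversed) for reads with 3 to 10 positions. The pooled report holds the other 5 libraries too, which by construction draws these values towards the mean of all libraries. Counting reads in pairs alone as mapped reversed deleted minus floxed after release, to 0.688, and starved minus growing in deleted cells, to 0.810. Leaving out the growing pair reversed the mean intron difference, to -0.0893. With all fragments or all reads as denominator, a share equals the main share times the share of fragments counted. That second share was 95.7% in growing floxed and 94.1% in growing deleted cells, and 94.7% and 95.4% after release. Those reversals, and the 2 from counting pairs alone, thus follow from how many reads were in broken pairs or unmapped. Why the libraries differed in this, and the cause of the reversals among uniquely mapped fragments, was not tested.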

Other observations

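The tests in this part were chosen after the results were seen.

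Reads with exactly 2 match positions were more frequent in starved cells of both genotypes and in deleted cells of each condition, and a candidate explanation is mitochondrial mRNA. Mitochondrial genes have no introns, so their fragments would fall within exons, and parts of them have copies in the nuclear genome. In GENCODE M21, 32.4% of 150-base windows of the 13 mitochondrial protein-coding genes were found in exactly 2 annotated genes, against 9.34% of windows of nuclear single-exon protein-coding genes. In 3 or more genes these shares were 0.254% and 7.07%. The copies are annotated as unprocessed pseudogenes. Those of mt-Co1, mt-Atp6, mt-Co3, mt-Nd3, mt-Nd4l and mt-Nd4 lie together on chromosome 1 of GRCm38, from Gm28439 (start 24611535) to Gm29216 (end 24616197). A copy of mt-Co2 (mitochondrial chromosome, 7013 to 7696), which encodes a subunit of cytochrome c oxidase, lies there too (Gm28661), and another on chromosome 2 (Gm13341, 22587291 to 22587962). For mt-Co3 (8607 to 9390), another subunit of that enzyme, 99.8% of windows had exactly 2 genes, and for mt-Atp6 (7927 to 8607), a subunit of ATP synthase, 99.4%. The copies of mt-Co1 and mt-Nd4 were partial, with 23.6% and 59.2% of windows in exactly 2 genes. Windows of mt-Nd1, mt-Nd2, mt-Atp8, mt-Nd5, mt-Nd6 and mt-Cytb had 0. This shows that reads from parts of these genes could be sorted into the class that differed, not that they were, and counts per gene would be needed to tell. The search was for exact copies in annotated transcripts, not for places in the genome under the mapping and annotation of the reports.

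In deleted cells, a gain after starvation shared by reads with 2 match positions and by the combined 3 to 10 class is argued against. In floxed cells both shares were larger after starvation, so a shared gain stays open there. A gain in equal proportion is argued against for the combined class. From growing to starved floxed cells its share went from 2.46% to 2.57%, and that of 2 positions from 8.75% to 12.3%. Reads with more than 10 positions have no class among those mapped in pairs, so a gain of sequence in more copies was not tested. In floxed cells each single class within 3 to 10 had a larger share after starvation, such as 9 positions, from 0.0525% to 0.0777%. In deleted cells the single classes went both ways. From growing to starved deleted cells, reads with 9 positions went from 0.0538% to 0.07005% and those with 3 from 1.55% to 1.44%. Starved minus growing, reads with 3 to 10 match positions differed by 0.112 points in floxed cells and by -0.0742 points in deleted cells, while reads with exactly 2 positions differed by 3.50 and 5.81 points.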
